A study of Drosophila melanogaster and Drosophila mauritiana and Drosophila melanogaster x Drosophila mauritiana with 7 samples.

How the data were processed

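Testes of adult flies aged 0 to 5 days were the source of all RNA, per the labels' protocols. Small RNAs of 19 to 29 nt were selected on polyacrylamide gels (some labels give 18 nt as the lower limit), and the RNA-seq libraries were depleted of ribosomal RNA and made with a directional kit. There were 7 libraries, 4 of small RNA and 3 of RNA-seq, with 1 per group. Groups were taken from the sample labels.

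The values used were read counts as deposited by the authors, not scaled to library size. The tools were cutadapt 1.8.1, Bowtie 1.2.2, Bowtie 0.12.7 with the genome build dm6, per the submitters' processing notes. Their settings, the mismatches allowed and the source of the repeat annotation were not given in the sources used here. The transposon table holds read counts of the authors for 350729 distinct sequences of 23 to 30 nt in the hybrid, Hmr1 and D. mauritiana, with the number of genomic hits, 1 listed hit and 1 repeat annotation each, over 212 repeats. D. mauritiana reads were placed on a D. melanogaster build, so reads of diverged copies can be missing or under another repeat. The VRr table holds the authors' counts of y w sequences and repeats a sequence's count under each of 26 copies that it matches. Its strand sheets hold the same sequences and counts as the full sheet. The vasa table holds the authors' counts of reads on vasa exons of both species by strand and by other places they match. In that table the D. mauritiana small RNA sense reads of the D. melanogaster gene and their parts do not add up, and these parts are not reported. In all, 54 columns of per-sample values, the copy and vasa columns of the strand sheets, repeat counts of the full sheet and were not used.

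The total of the transposon table (175982 reads in the hybrid, 441146 in Hmr1 and 133204 in D. mauritiana) is not a library's depth, which was not given in the sources used here. Values per repeat are therefore shares of transposon reads, given per 1000000. A count of 3 reads corresponds to 17.0 per 1000000 transposon reads in the hybrid, 6.80 in Hmr1 and 22.5 in D. mauritiana. Shares have exact Clopper-Pearson and counts exact Poisson intervals at 95%, and ratios have intervals from the conditional binomial; medians have 95% ranges over 200 Poisson draws of the counts. Sequencing reads without molecular identifiers are not independent molecules, so these intervals cover counting error only. With 1 library per group there is no replicate check and no p-value.

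Log2 ratios used a pseudocount of 1 read and repeats with at least 100 reads in either library of a pair. The 7 fixed lists were telomeric elements, germline LINEs, gypsy-family elements reported in somatic gonadal cells, copia and roo/BEL, the mdg group, DNA transposons and recent invaders of D. melanogaster. The gypsy-family list stands in for the somatic cells of the testis sample, and 13 of its 16 names were found as 26 repeats; 0 of its names are in another list. Each list's median was set against 10000 random lists of the same size drawn within 5 bins of mean level. Random lists drew single repeats, while internal parts and long terminal repeats of an element can vary together. Percentiles of lists with such parts can therefore be too extreme. Named repeats were the 10 highest and 10 lowest log2 ratios of each comparison of the hybrid with a parent, the 5 most abundant of each library, and 2 to 4 of the most abundant members of each list. For repeats listed by copy the rule named the copies with most reads in D. mauritiana and the hybrid; the table holds y w, so the copies with most y w reads are named. Lists, naming rule and most alternatives were fixed before the data were examined.

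Ping-pong was measured as the share of 10-nt overlaps among 5′ overlaps of 1 to 20 nt at listed positions, with z over the other overlaps. Added after these values were seen were the share of reads whose first 10 nt are complementary to those of another read on the same repeat, with windows shifted by 1 to 6 nt as background, in points above and as a ratio to that background, and 10-nt pairs above the mean of other overlaps per 1000000 reads. Equal depth means libraries thinned to 133204 transposon reads. Strand relative to a transposon was not derivable from the table, so sense and antisense transposon RNAs were not analysed here, nor was the RNA-seq level of the VRr repeats. Since the VRr table covers y w, the comparison of hybrid and parents used small RNAs antisense to D. mauritiana vasa. Whether those small RNAs match VRr repeats was not tested. Gene names and neighbours came from a reference gene table of build dm6.

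The procedures were tested on simulated data. For the hybrid against Hmr1 (151 repeats, 26 list members, 100 rounds), a simulated log2 shift of 2 was recovered as 1.99, 100% of changed and 2% of unchanged lists reached the upper 2.5% of random lists, and a simulated 10-nt share of 33.5% was recovered as 33.7%. The simulated libraries shared the Hmr1 profile with counting noise only, and list members were drawn singly. The real log2 ratios had quartiles of -1.40 and 2.05, so these list rates need not hold for the data. Alternatives were scaling by the median of ratios, pseudocounts of 0.1 and 10, no minimum, a minimum of 1000 reads, 23 to 29 nt, each position or sequence counted once, VRr reads without the copy with most reads and at 24 to 28 nt, and vasa reads per transposon read. Alternatives added after the data were seen were synonyms of list names, leaving out the 100 most abundant sequences of each library, single-hit sequences, equal depth, the other ping-pong measures, vasa scaling outside the gypsy-family list, both ways to assign vasa reads shared by the species, and parents at equal reads within and outside the gypsy-family list. Software was Python 3.11.15 with NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and Matplotlib 3.10.9.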

Results

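Testis RNA from adult flies was profiled in D. melanogaster, D. mauritiana and their F1 hybrid. The hybrid came from D. melanogaster carrying Hmr1, an allele of the hybrid incompatibility gene Hmr, and wild-type D. mauritiana. Small RNA libraries covered 4 genotypes (D. melanogaster y w, D. melanogaster Hmr1, D. mauritiana and the hybrid), and RNA-seq libraries covered Hmr1, D. mauritiana and the hybrid. Each group held 1 library, so no difference below has a replicate check and no p-value is given. Intervals are exact 95% intervals that cover counting error only. The study addressed piRNA production in the testis, with a focus on the vasa-related repeats (VRr) of the D. melanogaster X chromosome, and on transcripts of these repeats and of vasa. The table of transposon small RNAs of 23 to 30 nt held 175982 reads in the hybrid, 441146 in Hmr1 and 133204 in D. mauritiana. The table of VRr small RNAs held 137899 reads of y w.

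The first question was whether the VRr repeats produced piRNAs, which was answerable for y w. VRr small RNAs of 23 to 30 nt made up 114659 reads (113996 to 115325) in 2719 distinct sequences. They lay on build dm6 between X:21819609 and X:22371850, an interval that overlaps 21 annotated genes from CG40813 to CG41562. Almost all of them came from the plus strand, with 112391 reads or 98.0% (97.9 to 98.1), against 2268 reads from the minus strand. Without reads that match the copy with most reads, 13193 reads were left, with 84.7% on the plus strand. Plus-strand reads started with T in 87.4% (87.3 to 87.6), the first-base preference of primary Piwi-bound RNAs, and had A at base 10 in 8.53% (8.37 to 8.70). Minus-strand reads showed the opposite, with T first in 26.5% (24.7 to 28.4) and A at base 10 in 68.7% (66.7 to 70.6), the base that faces a first U in a ping-pong pair. The plus-strand values rested on abundant sequences: with each sequence counted once, T came first in 46.6% and A stood at base 10 in 23.5%. The most frequent length was 25 nt on both strands, with 29.3% of plus-strand and 25.7% of minus-strand reads of all lengths.

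Reads were unevenly placed among the 26 VRr copies, and most matched many of them. VRr18 and VRr20 each matched 101466 reads, VRr19 matched 101361, VRr23 matched 98775, VRr21 matched 92178 and VRr24 matched 60294. VRr1, VRr2, VRr4, VRr6 and VRr7 each matched 56821 reads. A read matched a median of 12 copies, 12.3% of reads (12.1 to 12.5) matched all of them, and 1.89% (1.81 to 1.97) matched 1 copy. These copy values therefore share reads and cannot be added. The most abundant sequence, TATAGCACACTTTTGTATCGGCGTC at X:22276032 to 22276056, had 8413 reads. Opposite-strand 5′ ends overlapped by 10 nt in 8.69% of the overlaps of 1 to 20 nt (z = 3.52). With each distinct position counted once this share was 4.91% (z = -0.12), so the excess by position rested on abundant sequences. By the first 10 nt of sequences, a measure added after the data were seen, 78.8% of reads had a partner over a background of 31.5% (15.2 to 43.8 over shifts of 1 to 6 nt). This measure counts a read when any other read, however rare, has the complementary start. Minus-strand reads were 1.98% of reads, so it is not a share of reads in opposite-strand pairs.

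**Figure D1:**
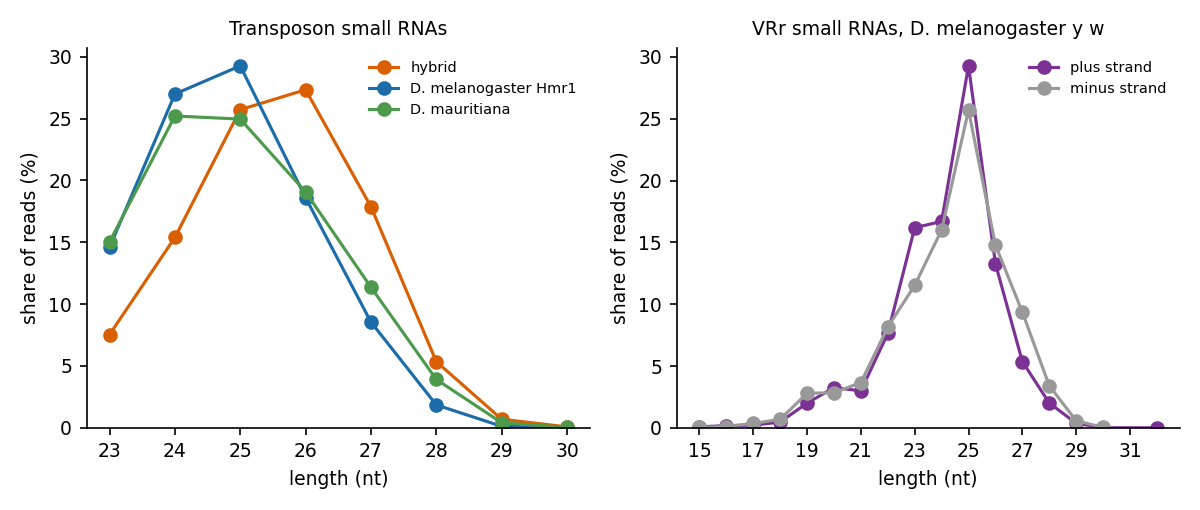
Length of small RNAs in nucleotides (x axis) against the share of reads in percent (y axis). Left, transposon small RNAs of the hybrid, Hmr1 and D. mauritiana; the hybrid peaked at 26 nt (27.3%) and Hmr1 at 25 nt (29.3%). Right, VRr small RNAs of y w by strand, each strand's lengths as shares of that strand's reads; both peaked at 25 nt.

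The hybrid and its parents were compared through small RNAs antisense to D. mauritiana vasa, which encodes a germline DEAD-box helicase. The values used do not show whether these small RNAs match VRr repeats. Nearly all such antisense reads also matched a D. melanogaster locus outside vasa, and this class was by far the most abundant in Hmr1. It held 6865 reads (6704 to 7029) in Hmr1, 337 (302 to 375) in the hybrid and 16 (9.15 to 25.98) in D. mauritiana. As deposited, the hybrid stood at 0.0491 (0.0439 to 0.0548) of Hmr1 and was 21.1-fold (12.8 to 37.3) above D. mauritiana. It stood at 0.0980 of the mean of both parents. Per transposon read of the same library the ratio to Hmr1 was 0.123 (0.110 to 0.137), the ratio to D. mauritiana was 15.9 (9.67 to 28.2), and the ratio to the parental mean was 0.244. Antisense reads made up 98.1% (97.7 to 98.4) of small RNAs on D. mauritiana vasa exons in Hmr1, 92.2% (89.0 to 94.7) in the hybrid and 66.7% (44.7 to 84.4) in D. mauritiana. On D. melanogaster vasa exons the antisense share was 4.04% (2.10 to 6.95) in Hmr1, 16.7% (3.58 to 41.4) in the hybrid with 3 of 18 reads, and 0 of 2 reads in D. mauritiana. The ratio to Hmr1 moved by more than 1.5 times with the scaling, and full library totals were not used here.

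**Figure D2:**
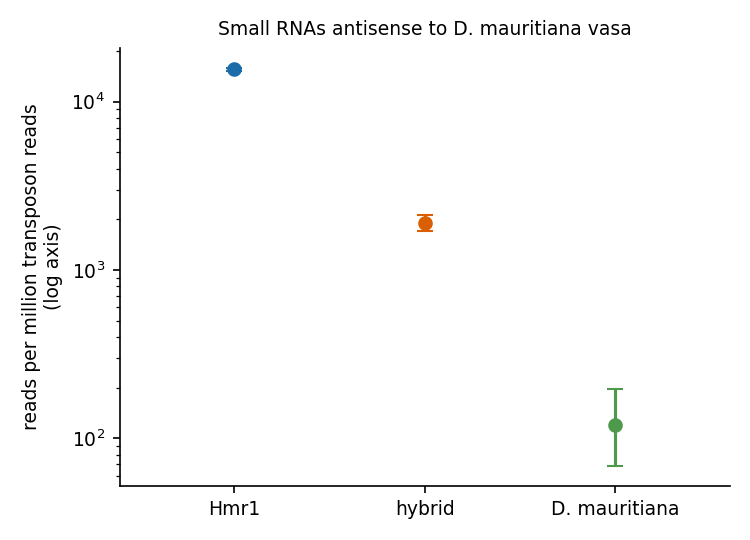
Small RNA reads antisense to D. mauritiana vasa that also match a D. melanogaster locus outside vasa, per 1000000 transposon reads (y axis, log axis), in each library (x axis). Points are single libraries and bars are exact 95% Poisson intervals; the values were 15562 in Hmr1, 1915 in the hybrid and 120.1 in D. mauritiana.

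RNA-seq then asked which vasa transcripts the testes held. In the hybrid, 30 sense reads (20.2 to 42.8) lay on vasa exons, against 84 (67.0 to 104.0) in Hmr1 and 117 (96.8 to 140.2) in D. mauritiana. Of the 28 hybrid reads that belonged to 1 species, 8 were of D. mauritiana vasa, a share of 28.6% (13.2 to 48.7). In Hmr1, 0 of 83 such reads were of D. mauritiana vasa, which by a limit of 3 reads allows a share of up to 3.61%. In D. mauritiana 113 of 113 were of its own vasa, and by the same limit 0 reads of the other species allow a share of up to 2.65%. The totals of these libraries were not given in the sources used here, so the vasa counts are not levels. The table's own remark says that the hybrid does not express D. melanogaster vasa, while the table lists 20 sense reads of that gene alone in the hybrid.

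Transposon small RNAs of the hybrid differed from those of Hmr1 most clearly in the gypsy family of endogenous retroviruses, several of which are active in somatic cells of the gonad. The fixed list of this family had 26 measured members (internal parts and long terminal repeats counted separately) and took 38.4% (38.1 to 38.6) of transposon reads in the hybrid against 7.08% (7.005 to 7.16) in Hmr1. Its median log2 ratio was 2.75, above that of all 10000 random lists of matched level (percentile 100), with 23 members at least 2-fold higher and 0 at least 2-fold lower. Gypsy5_I-int stood at 3.57, with a ratio of 11.8 (11.2 to 12.5). Gypsy10_I-int stood at 3.55, TABOR_I-int at 3.15, Gypsy_I-int at 3.14 and Stalker2_I-int at 3.09, whereas ROVER-LTR_DM differed by 0.00. Other repeats with the highest log2 ratios were LINEJ1_DM (3.87), TRANSPAC_I-int (3.84), Gypsy1-LTR_DM (3.63), TIRANT_I-int (3.35), Gypsy10_LTR (3.34), BARI1 (3.30) and Gypsy_LTR (3.28). Of these, LINEJ1_DM, TRANSPAC_I-int and BARI1 lay between the parents, with log2 ratios of -2.14, -1.82 and -2.40 to D. mauritiana. TRANSPAC_I-int and BARI1 had 38 and 26 reads in Hmr1. Gypsy1-LTR_DM, TIRANT_I-int, Gypsy10_LTR and Gypsy_LTR lay above both parents.

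The lowest ratios of the hybrid to Hmr1 included a telomeric fragment and the abundant Hmr1 repeats PROTOP and NINJA_I-int. TART_B1 stood at -4.72 with 2 hybrid reads and a ratio of 0.0254 (0.00306 to 0.0932). DIVER2_LTR followed at -3.89, PROTOP at -3.65, NINJA_I-int at -3.52, Transib5 at -3.13 and PROTOP_A at -3.04. Invader2_I-int stood at -2.91, G6_DM at -2.89, NINJA_LTR at -2.66 and G3_DM at -2.63 with 7 hybrid reads. With a pseudocount of 10, TART_B1 stood at -2.78 and G3_DM at -1.64. D. mauritiana had 3 reads of TART_B1, 3 of Transib5 and 2 of G3_DM, and the hybrid was not below it beyond counting error. The other repeats named so far in this paragraph lay below both parents. The copia and roo/BEL list had a median of -1.38 (percentile 2.77), with 8 of 13 members at least 2-fold lower, although ROO_I-int (-0.38) and Copia_I-int (-0.18) lay close to Hmr1. The germline LINE list, non-LTR retrotransposons of the germline, had a median of -0.96 (percentile 10.6), with 7 of 15 members at least 2-fold lower, such as DMRT1B at -2.45 and G2_DM at -2.38. The medians were -0.78 for the mdg group (percentile 8.01; MDG3_I-int -1.14, MDG1_I-int 1.99) and -0.49 for DNA transposons (percentile 29.8; HOBO -0.49, TRANSIB2 -1.62). For the telomeric list the median was 1.00 (percentile 59.0; HETA 1.00, TAHRE 2.53, TART -0.31), and for recent invaders 0.38 (percentile 64.2; DM412 3.11, BLOOD_I-int 2.14, I_DM -0.26).

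Over all 151 repeats with at least 100 reads in either library, the median log2 ratio of hybrid to Hmr1 was -0.15 (-0.22 to 0.035 over Poisson draws), with 52 at least 2-fold higher and 52 at least 2-fold lower. Values are shares of transposon reads, so a high share of one family lowers the others. Scaling by the median of ratios moved the median by -0.17, and it was 0.36 with no minimum of reads. With single-hit sequences it was -1.30, over the repeats that still reached 100 reads. By class, LTR elements of the Gypsy type took 73.7% of hybrid reads against 32.8% in Hmr1, a ratio of 2.25 (2.23 to 2.27). LINE elements took 13.7% against 32.5% (ratio 0.420), Pao elements 5.15% against 14.8% (ratio 0.347) and DNA transposons 2.43% against 14.2% (ratio 0.171).

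Against D. mauritiana the gypsy family was again higher in the hybrid, with 8.90% (8.75 to 9.05) of transposon reads in D. mauritiana. The list's median was 2.27 (percentile 99.98), with 23 of 26 members at least 2-fold higher, including DM176_I-int at 6.39 (ratio 86.6, 61.6 to 126.0) and QUASIMODO_I-int at 3.44. Stalker3_LTR stood at 6.94 and RSP, the Responder satellite, at 6.33, each against 1 read of D. mauritiana, with ratios of 245.2 (43.7 to 9716) and 159.7 (28.4 to 6338). Gypsy6_LTR stood at 6.07 against 2 reads (ratio 100.7, 27.6 to 835.6), GTWIN_LTR at 5.76 against 5 reads (ratio 64.9, 27.6 to 201.0) and BARI_DM at 5.37 against 3 reads (ratio 55.0, 18.6 to 268.8). Gypsy2_I-int followed at 4.79, Copia2_LTR_DM at 4.69 against 6 reads, Jockey2 at 4.63 and QUASIMODO_LTR at 4.60. With a pseudocount of 10 these low counts gave 4.52 for Stalker3_LTR, 3.93 for RSP, 4.12 for Gypsy6_LTR, 4.47 for GTWIN_LTR, 3.73 for BARI_DM and 3.55 for Copia2_LTR_DM. Among the repeats named here as higher than in D. mauritiana, RSP and Copia2_LTR_DM stood at 0.418 and 0.712 of Hmr1. The others lay above both parents. The lowest were DMRT1C (-6.37), OSVALDO_I-int (-5.88 with 6 hybrid reads, and -4.73 with a pseudocount of 10), G5_DM (-5.72), TRANSIB1 (-5.32), Gypsy8_I-int (-5.29), MAX_LTR (-4.30), TOM_I-int (-4.30), LOOPER1_DM (-4.11), MAX_I-int (-4.05) and R2_DM (-3.94). Of these, G5_DM, TRANSIB1 and Gypsy8_I-int lay below both parents. The hybrid stood above Hmr1 for DMRT1C (ratio 2.04), TOM_I-int (1.90), LOOPER1_DM (2.82), MAX_I-int (1.21) and R2_DM (4.42). Hmr1 had 38 reads of DMRT1C, 29 of TOM_I-int, 16 of LOOPER1_DM and 17 of R2_DM. OSVALDO_I-int and MAX_LTR did not differ from Hmr1 beyond counting error.

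List medians against D. mauritiana were -2.55 for copia and roo/BEL (percentile 0.285), with 10 of 14 members at least 2-fold lower and ROO_I-int at 3.94. They were -1.65 for germline LINEs (percentile 6.63), with 12 of 17 at least 2-fold lower, and -2.22 for DNA transposons (percentile 4.47). The mdg group had -0.10 (percentile 35.4), the telomeric list 1.21 (percentile 81.7) and recent invaders 1.72 (percentile 87.1). Over 155 repeats the median was 0.23, with 64 at least 2-fold higher and 62 at least 2-fold lower. Sequences with a single genomic hit gave -0.55, a change of sign.

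The hybrid was also placed against both parents together. Of 165 measured repeats, 57 lay above both parents and 46 below both by their exact intervals, and 62 lay between them or within error. In the gypsy-family list 25 of 26 members lay above both. Of the germline LINE list 9 of 17 lay below both, and Jockey2 was the 1 member above both. Among the Pao class 0 of 15 lay above and 8 below both. The most abundant repeats of the hybrid were DM412 (55932 per 1000000 transposon reads), TABOR_I-int (46829), STALKER4_I-int (45454), Gypsy4_I-int (43124) and Gypsy5_I-int (41885). With only sequences of a single genomic hit, the number of repeats at least 2-fold above both parents was 17, against 39 with all sequences.

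**Figure D3:**
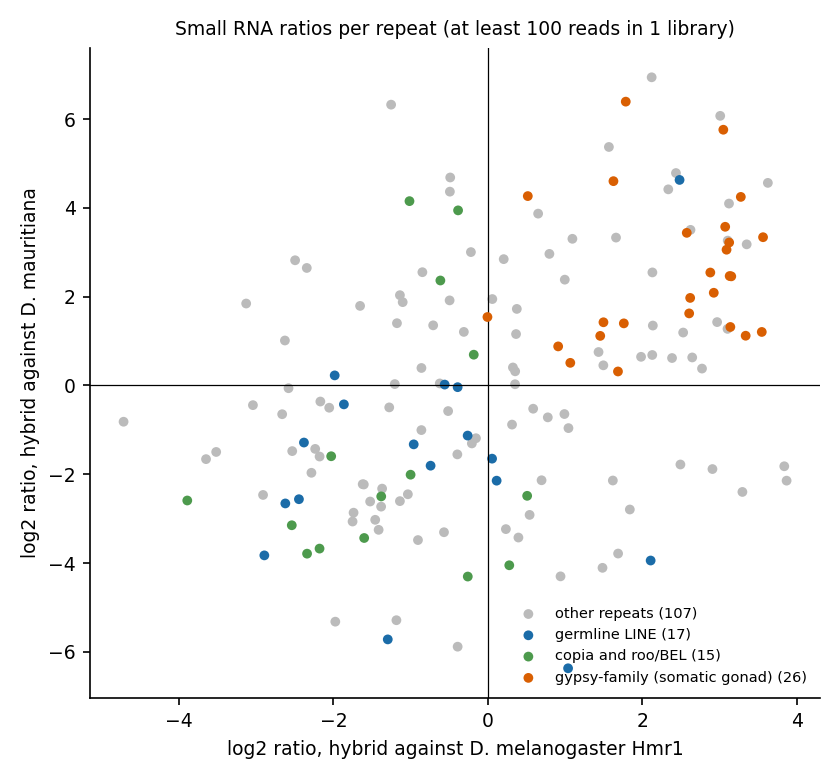
Log2 ratio of the hybrid to Hmr1 (x axis) against its log2 ratio to D. mauritiana (y axis), 1 point per repeat with at least 100 reads in a library, coloured by fixed list. Of the 26 gypsy-family points, 25 lie above both parents, with medians of 2.75 and 2.27.

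The parents themselves differed in other families. The most abundant repeats were Baggins1 (98790 per 1000000), NINJA_I-int, PROTOP, R1_DM and NOMAD_I-int in Hmr1, and MAX_I-int (66470 per 1000000), BATUMI_I-int, DMCR1A, R1_DM and Gypsy12_I-int in D. mauritiana. ROO_I-int was 20.2-fold (17.56 to 23.4) higher in Hmr1, and MAX_I-int stood at 0.0497 (0.0470 to 0.0526) of D. mauritiana. The gypsy-family list had a median of -0.23 (percentile 56.0), germline LINEs -0.37 (percentile 42.9), copia and roo/BEL -1.01 (percentile 21.03) and the mdg group -0.06 (percentile 62.2). DNA transposons had -0.60 (percentile 47.5), the telomeric list 1.39 (percentile 90.6) and recent invaders -0.17 (percentile 51.8). Over 160 repeats the median was -0.28, with 51 at least 2-fold higher in Hmr1 and 62 at least 2-fold lower. Scaling by the median of ratios moved it by 0.18, and single-hit sequences gave 0.41 for all repeats and 0.26 for germline LINEs, both with a change of sign.

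Transposon small RNAs were examined for ping-pong pairs, whose opposite-strand 5′ ends overlap by 10 nt. By genomic position, 10-nt overlaps made up 31.6% of overlaps of 1 to 20 nt in D. mauritiana (z = 20.6), 12.9% in the hybrid (z = 11.4) and 9.90% in Hmr1 (z = 7.95). With all libraries thinned to the transposon reads of D. mauritiana, called equal depth here, they were 12.7% in the hybrid and 11.8% in Hmr1. Since each sequence has 1 listed position, a measure on the first 10 nt of sequences within each repeat was added after these values were seen. By it 41.3% of reads in D. mauritiana, 33.7% in Hmr1 and 7.22% in the hybrid had a partner at equal depth, over backgrounds of 4.05%, 10.1% and 2.92%. In points above background at equal depth the hybrid (4.30) lay below Hmr1 (23.6) and D. mauritiana (37.3). As a ratio to background the hybrid lay below D. mauritiana (10.2) at both depths, with 2.47 against 3.35 in Hmr1 at equal depth and 2.37 against 2.27 at full depth. Across 19 versions computed (4 measures under up to 5 settings), the hybrid lay below D. mauritiana in 19 and below Hmr1 in 11, so its order against Hmr1 depended on the measure. Over 77 repeats measured singly at equal depth, the points above background had medians of 6.06 in the hybrid, 12.8 in Hmr1 and 29.1 in D. mauritiana, with the hybrid below Hmr1 in 60 and below D. mauritiana in 70. In the gypsy-family list at equal depth the 10-nt share by position was 24.8% in D. mauritiana (66 of 266 pairs, z = 8.82). It was 3.98% in the hybrid (14 of 352, z = -1.54) and 10% in Hmr1 (10 of 100, z = 1.73), pairs too few to order these libraries. By the first 10 nt, 1.27% of list reads in the hybrid had a partner over a background of 1.19%, 9.12% over 2.26% in Hmr1 and 12.98% over 1.52% in D. mauritiana.

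**Figure D4:**
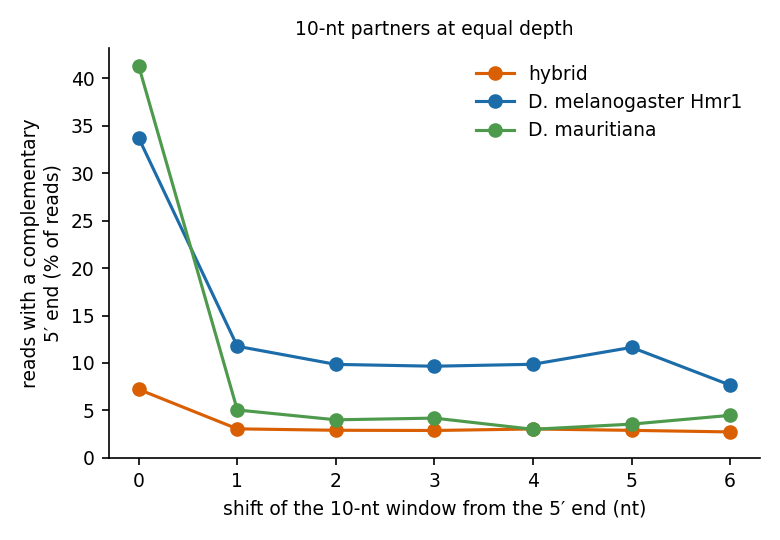
Share of reads whose 10-nt window is complementary to the 5′ end of another read on the same repeat (y axis, percent) against the shift of that window from the read's 5′ end (x axis, nt), at equal depth; lines are single libraries. At shift 0 the shares were 41.3% in D. mauritiana, 33.7% in Hmr1 and 7.22% in the hybrid, and shifts of 1 to 6 nt give the background.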

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

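No explanation was tested here. The VRr table of y w has a further column for vasa that no comparison uses, and it was not empty. It held 7 reads (2.81 to 14.4) in 3 sequences of 19 to 20 nt, above the limit of 3 reads set for a count of 0, and under the length of most piRNAs of these repeats.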

How the results depend on the processing

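Single-hit sequences, synonyms, leaving out the most abundant sequences, equal depth, the first-10-nt measures, both assignments of vasa reads shared by the species and vasa scaling outside the gypsy-family list were chosen after seeing the data; the cause of a shift was not tested. Over alternatives, 78 main values stayed within the counting interval of the main value (counts of repeats and of VRr reads within 1.5 times), 48 moved beyond it and 3 values whose interval excluded 0 changed sign. Some of those that moved set unlike quantities side by side, such as points or ratios to background beside a 10-nt share, or distinct sequences beside reads. For these the tally says nothing of the dependence on processing. The median of hybrid against Hmr1, whose interval held 0, changed sign too with no minimum. For named repeats 643 of 690 stayed the same and 46 moved, and DMCR1A against Hmr1 changed sign (-0.058 under the median of ratios). Log2 medians follow. Median of ratios: hybrid against Hmr1 -0.33 (gypsy list 2.58), Hmr1 against D. mauritiana -0.091 (gypsy list -0.042, LINE -0.18). No minimum: hybrid against Hmr1 0.36 (LINE -0.74), against D. mauritiana 0.39, with 57 repeats at least 2-fold above both parents against 39 and 37 below both against 33. Minimum of 1000 reads: hybrid against Hmr1 -0.49 (LINE -1.41), LINE against D. mauritiana -2.56, Hmr1 against D. mauritiana -0.063 (LINE -0.24), and 21 repeats above both parents. Synonyms: gypsy list 2.62 against Hmr1, gypsy list of the parents -0.075 (LINE -0.24). Without the most abundant sequences: hybrid against Hmr1 -0.30 (gypsy list 2.55), parents -0.12. Single-hit: hybrid against Hmr1 -1.30 (gypsy list 2.25, LINE -1.25), against D. mauritiana -0.55 (LINE -2.75), parents 0.41 (LINE 0.26), and 17 repeats above both parents. Under both pseudocounts and 23 to 29 nt medians over all repeats and over the gypsy and LINE lists stayed within their intervals, with -0.056 for hybrid against Hmr1 at a pseudocount of 10.

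The 10-nt share with each position once was 10.3% in the hybrid, 7.41% in Hmr1 and 20.2% in D. mauritiana, and 11.8% in Hmr1 at equal depth. At full depth the first-10-nt measure gave 4.81, 25.9 and 37.3 points above background in these libraries, or 2.37, 2.27 and 10.2 times background. With each sequence counted once it gave 3.96 points in the hybrid, 9.76 in Hmr1 and 19.3 in D. mauritiana, or 2.06, 1.603 and 5.603 times background. VRr reads numbered 13193 without VRr18, with 84.7% on the plus strand, and 2719 with each sequence once, with 83.3%. With each sequence once, T came first in 46.6% of plus and 29.9% of minus sequences, and A stood at base 10 in 23.5% and 50.5%. With each distinct position once, the 10-nt share was 4.91%. Weighted by reads, the first-10-nt measure of VRr sequences, also chosen after seeing the data, was 47.3 points above background. The vasa-antisense ratio to Hmr1 was 0.123 per transposon read and 0.186 outside the gypsy list, and that to the parental mean 0.244. Not run, since the tables used do not allow them: y w as the D. melanogaster library, 21-nt transposon reads, perfect matches, y w VRr reads per transposon read, median ratios over copies, transposon sense and antisense, vasa sites or windows, and VRr levels in RNA-seq. No paired analysis was possible because each group held 1 library. A count of 3 reads stood for most in D. mauritiana, with 22.5 per 1000000 transposon reads.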

Other observations

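Except for the first test of the parental origin of gypsy-family sequences, the tests in this part were chosen after the results were seen. The flamenco locus (flam, X:21631891 to 21790731), the main somatic piRNA cluster of the gonad and a store of gypsy-family fragments, held a higher share of transposon small RNAs in the hybrid than in either parent. Listed hits there made up 5.04% (4.93 to 5.14) of reads in the hybrid, 0.519% (0.498 to 0.541) in Hmr1 and 0.142% (0.122 to 0.164) in D. mauritiana, a ratio of 9.71 (9.27 to 10.2) to Hmr1. Among sequences with a single genomic hit the shares were 36.0%, 4.36% and 1.09%. Of all listed hits there in the hybrid, 99.1% were on the plus strand, and Gypsy2-I_DM (14.7% of them), IDEFIX_I-int (11.01%) and ZAM_I-int (10.5%) led. A separate Gypsy5_I-int site between lncRNA:CR44765 and CG11106, X:11195438 to 11199546, held 20.6% (19.998 to 21.1) of single-hit reads in the hybrid and 2.09% (1.95 to 2.24) in Hmr1, a ratio of 9.84 (9.13 to 10.6). These loci were picked after their values were seen, the labels do not give the direction of the cross and so not which species' X and Y chromosomes the hybrid carried, and D. mauritiana sequences that differ from dm6 are undercounted at them.

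Other loci held higher shares in Hmr1. A stretch of 2L between CG13970 and CG10651, 20104910 to 20110017 and led by G6_DM, held 6.27% of single-hit reads in Hmr1 and 0.562% in the hybrid, a ratio of 0.0896 (0.0733 to 0.109). The Y chromosome held 13.8% of single-hit reads in Hmr1, 6.45% in D. mauritiana and 0.959% in the hybrid, and the X chromosome 30.7%, 13.1% and 71.3%. The most abundant Hmr1 sequence, TGACAGCTTCTAGTTCGTCTAGGAC of Baggins1 with a listed hit at X:22275672 to 22275696, inside the VRr interval, had 24119 reads per 1000000 in Hmr1, 250.03 in the hybrid and 247.7 in D. mauritiana. A PROTOP sequence, TAACAAGATGCATACGATGTGGCT with a listed hit at Y:854697 to 854720 between ARY and Su(Ste):CR42422, had 12411, 56.8 and 75.1 per 1000000. Transposon reads with listed hits in the VRr interval made up 8.90% in Hmr1, 6.82% in the hybrid and 0.402% in D. mauritiana, whereas among single-hit sequences the hybrid stood higher, with 7.53% against 3.44% in Hmr1 (ratio 2.19, 2.03 to 2.35) and 1.05% in D. mauritiana.

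Gypsy-family small RNAs stood higher in the hybrid than in both parents. Loss of D. mauritiana reads in mapping to dm6 would by itself leave a hybrid that mixes its parents evenly between them. Of the list members, fixed before the data were examined, 25 of 26 lay above both. The mix can differ by chromosome, since which species' X and Y the hybrid carried was not given. Loss as the whole cause under an even mix is therefore argued against, and loss as a contribution stays open. Abundant Hmr1 sequences taking reads from the rest are argued against as well, since without them the median against Hmr1 was 2.55. A smaller share of germ cells, as the whole cause or a contribution, cannot be told apart from a change within cells: log2 ratios of the members spanned 3.57, but members may hold germline reads, and 4 flam windows and the Gypsy5_I-int site lay closer together, 6.54-fold to 10.2-fold above Hmr1. Germline LINE medians were below 0 against both parents (percentiles 10.6 and 6.63), the telomeric list had 1.00 and 1.21, and the 10-nt signal of the hybrid lay below Hmr1 in 11 of 19 versions, and no cell counts were used.

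Vasa-antisense small RNAs were lower in the hybrid than in Hmr1. Dilution by small RNAs of the gypsy-family list as the whole cause is argued against, since outside that list the ratio was 0.186 (0.166 to 0.207). All LTR elements of the Gypsy type, listed or not, took 73.7% of hybrid reads against 32.8% in Hmr1. Dilution by those outside the list was not tested. A fall shared by D. melanogaster germline small RNAs cannot be told apart from one of its own: the log2 ratio of -3.02 lay at percentile 4.8 of 125 repeats outside the gypsy-family list, 6 of which were lower. Genotype stays open, untested.

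The 10-nt signal was weaker in the hybrid than in D. mauritiana in all 19 versions computed. Sequencing depth and dilution by small RNAs of the gypsy-family list are argued against, since over the measures the hybrid reached at most 40.1% of D. mauritiana at equal depth and 43.2% outside that list. A part played by abundant sequences stays open: without the 100 most abundant of each library it reached at most 40.9%, but with each position counted once 50.7%. Loss of D. mauritiana reads on dm6 and species differences were not tested.

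D. melanogaster alleles as the source of the hybrid's gypsy-family small RNAs were a hypothesis with a prediction made before its result was seen. With parents at equal depth, 13.5% of hybrid transposon reads had a sequence seen in Hmr1 but not D. mauritiana, 5.93% the reverse, 4.14% in both and 76.5% in neither. Among gypsy-family reads seen in 1 parent, 63.0% (62.1 to 63.9) were of Hmr1, against 72.7% (72.1 to 73.3) for other repeats. The bounds set before were over 80% and above the other repeats for this source, and under 50% or below the other repeats against it. The lower share met the last bound, against this source. At that depth Hmr1 had 9423 list reads and D. mauritiana 11852, against 123781 and 121352 elsewhere, which by itself lowers the Hmr1 share in the list. A further test, chosen with its bounds after the first was seen, put the parents at equal reads within the list, and the share was 67.7% (66.9 to 68.5), against 72.3% (71.7 to 72.9) elsewhere. Its bound against this source was under 50% and left out the comparison with other repeats. The share was thus a majority for Hmr1, yet still lower than elsewhere and below 80%. Unequal list reads therefore did not account for all of the shortfall. Single-hit reads at flam numbered 6970 in the hybrid, 1719 in Hmr1 and 119 in D. mauritiana, which goes with D. melanogaster alleles, although D. mauritiana sequences are undercounted on dm6. The prediction made before was not met, and its bound against D. melanogaster alleles as the source was. That source still cannot be told apart from alleles of both species, as 79.3% of list reads had been seen in neither parent in the first test.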
